A study of Homo sapiens with 8 samples.

How the data were processed

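4C-seq signal was analysed in 8 libraries of the Calu3 line, with NC or BACH1 siRNA and the -20.9 kb or -80.1 kb CFTR viewpoint, 2 libraries per group. Groups follow the sample titles, and replicates were numbered for reference only. Per the labels, 6 libraries were made with a 2012 method and 2, replicate 2 of both siRNAs at -20.9 kb, with a 2020 method.

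The deposited files hold 4C signal near the viewpoint, per the labels and the values: 144 columns of signal at positions 1 kb apart. These were read as 48 triplets of a middle, upper and lower value, for windows of 2 to 49 kb, from the order of the values and the missing edges, since the files have no header. The build is hg19, per the submitters' processing notes. The aligner, the normalization and the software are not given in the sources used here. The values are fractional and were scaled before they were deposited, in a way the sources used here do not describe. No read counts are in the values: low values were not whole multiples of a step, so depth is unknown and no counting interval is given. In each library 34.2% to 68.2% of positions share 2 low values, and the higher, called the floor, ran from 0.000275 to 0.0156 in deposited units, a 56.7-fold range. Windows above the floor numbered 48 to 112 of 176 per library. Values at the floor have no order.

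The middle value of the 5 kb windows was taken in 180 non-overlapping windows over the 900 kb that all files cover. Windows within 10 kb of a library's own viewpoint were set to missing. Each library was divided by its sum over the remaining windows and expressed in percent. Windows at or below the floor are part of this sum and held 0.636% to 32.2% of it. A window was kept if positive in at least 2 libraries of a viewpoint, which removed 1 window (117164485 to 117169484, at 0 in every library). Changes are on the log2(percent + pseudocount) scale, with a pseudocount of 0.0103%, the 5% quantile of positive values. The pseudocount shrinks changes of low windows. Changes of windows at the floor still follow the heights of the floors.

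All 8 libraries were fitted together with limma 3.58.1 in R 4.3.3 (lmFit, and eBayes with trend), with 4 groups and a protocol term, and Benjamini-Hochberg adjustment at 0.05. The estimated spread came wholly from the trend over signal level. Elements were tested in 5 kb windows centred on them in the same fit, adjusted over the list alone. Interval shares were compared by exact two-sided permutation. Within the -20.9 kb viewpoint, libraries with the same protocol label deviated together from their group means (r = 0.614 across 63 windows above the floor), and the protocol term carries this pairing. Figures were drawn with matplotlib 3.10.9.

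Element positions are offsets from the translation start estimated from the signal peaks and are good to about 1.1 kb. No annotation of hg19 was used: the positions of introns 11 and 23, +6.8 kb and +48.9 kb, and of the WNT2, ASZ1 and CTTNBP2 starts, rest on known gene structure and are approximate. The order of these genes was checked in a GRCh38.p14 gene table, whose coordinates were not used. Starts of CAV2, CAV1, MET, CAPZA2, ST7, LSM8 and ANKRD7 lie outside the region analysed here.

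The elements and genes, and the rule for other windows, were fixed before the data were examined: windows past the threshold, and otherwise the 3 largest changes each way whose libraries do not overlap. The fit was tested on simulated data with the trend's spread. Changes were planted in 12 windows among those above the floor, in 100 simulations of 175 windows each. At a log2 change of 2 the fit recovered 49.8% at the -20.9 kb viewpoint and 61.5% at -80.1 kb. Calls in other windows numbered 0.76 and 0.72 per simulation. At a change of 1 it recovered 5.33% and 4.50%. The simulated noise was independent, without floors, protocol differences or deviations shared by libraries, so recovery in the real data may differ. Alternatives covered scaling, window size, pseudocount, filter, excluded zone, protocol term, pairing, variance trend, libraries in the fit, region and each library left out; others, chosen after seeing the data, concerned the floor, the scaling above it and the upper value.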

Results

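The contacts of the CFTR locus on chromosome 7 were measured by 4C-seq in Calu3, a human lung adenocarcinoma line with an airway epithelial character that expresses CFTR, the gene of the chloride channel altered in cystic fibrosis. 4C-seq ligates DNA fragments that lie close together in the nucleus and reads out everything joined to 1 chosen fragment, the viewpoint. Cells had received an siRNA against BACH1, a transcription repressor of the oxidative stress response, or the siRNA labelled NC, the control arm. The series asks how contact frequencies between regulatory elements of CFTR change on knockdown of BACH1. There were 8 libraries in 4 groups of 2, one group per siRNA at each of 2 viewpoints, named by distance from the CFTR translation start: the -20.9 kb insulator and the -80.1 kb element at the 5' boundary of the CFTR domain. The files hold normalised contact signal and no read counts, so the depth of each library is unknown. The level of BACH1 itself was not analysed here. The labels do not say that the libraries of a group came from separate cultures, so the spread between libraries may be technical. Limma took this spread wholly from a trend over signal level across windows. Its SEs and p-values therefore do not follow the spread of the libraries compared. The same SE of the log2 change served both viewpoints (0.25 at the -35 kb airway enhancer).

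Libraries with the same viewpoint in their titles peaked within 1 kb of each other. All 4 libraries titled -20.9 kb peaked at position 117097984 (hg19) at the finest resolution of the files, and those titled -80.1 kb peaked at 117040984 or, in NC siRNA replicate 1, at 117041984. The median peaks of the viewpoints gave 2 estimates of the translation start that differed by 2.2 kb, and their mean, 117119984, was used to place the elements. The free-text descriptions name a different viewpoint from the title in 6 of the 8 libraries, and libraries that share a title shared a peak whatever their description.

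Both viewpoints contacted the stretch between the 5' and 3' boundaries of the CFTR domain, and both had some signal just upstream of it. From the -20.9 kb viewpoint, the highest 5 kb window outside the 10 kb on either side of the viewpoint was 117084485 to 117089484, which holds the -35 kb airway enhancer and borders the excluded stretch. It held 8.44% ± 3.58 of the summed signal of a library with NC siRNA and 7.79% ± 0.675 with BACH1 siRNA (SD, n = 2 each). From the -80.1 kb viewpoint the same window was second highest, at 5.40% ± 0.0111 with NC siRNA and 5.77% ± 1.38 with BACH1 siRNA (SD, n = 2 each). The +48.9 kb element, at the 3' boundary past the end of the gene, was contacted from both: 1.70% ± 1.06 with NC siRNA from -20.9 kb and 2.21% ± 0.0510 from -80.1 kb (SD, n = 2 each). Intron 11 and intron 23, which lie between, were low, at 0.200% ± 0.158 and 0.238% ± 0.201 from -20.9 kb with NC siRNA (SD, n = 2 each). Between the -80.1 kb and +48.9 kb elements, 51 of 59 measured windows stood above each library's floor in all 4 libraries of the -20.9 kb viewpoint, and 37 of 61 in those of the -80.1 kb viewpoint. The floor is the higher of the 2 most repeated low values of a library. The window 117024485 to 117029484, upstream of the 5' boundary, held 3.82% ± 0.784 from -80.1 kb and 0.452% ± 0.120 from -20.9 kb with NC siRNA (SD, n = 2 each). It borders the stretch excluded at the -80.1 kb viewpoint. Within that stretch, 117034485 to 117039484 held 2.11% ± 0.480 from -20.9 kb with NC siRNA (SD, n = 2), with no value from -80.1 kb to set beside it. Upstream of -80.1 kb the numbers above the floor were 5 of 48 and 7 of 46 windows, and beyond +48.9 kb they were 7 of 69 and 3 of 69.

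**Figure D1:**
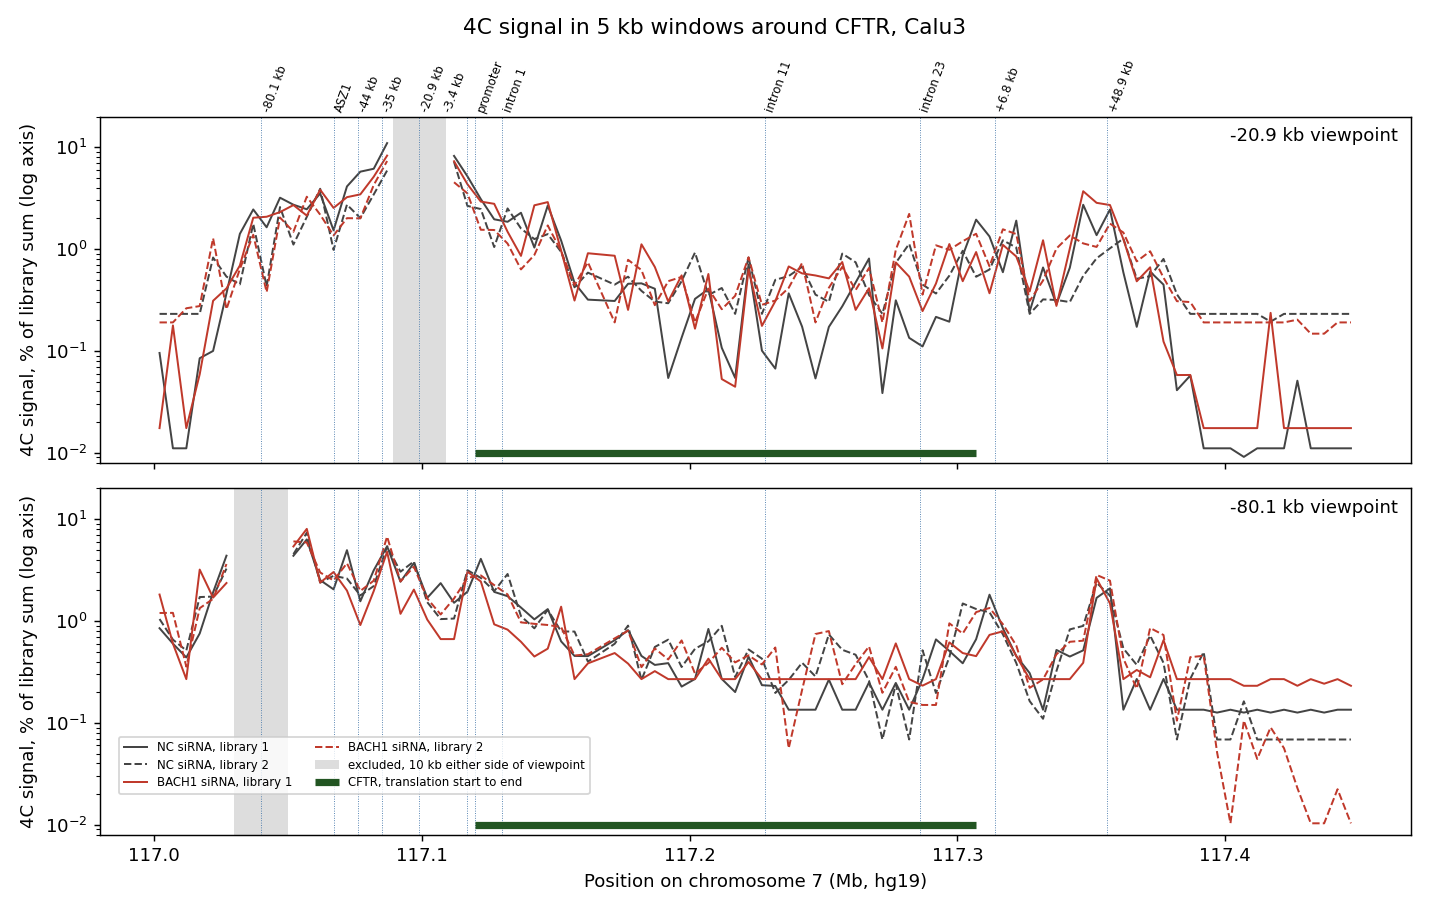
4C signal in 5 kb windows, as percent of the library's summed signal on a log axis, against position on chromosome 7 (hg19), for the -20.9 kb viewpoint (top) and the -80.1 kb viewpoint (bottom). Each line is 1 library (grey NC siRNA, red BACH1 siRNA), the shaded band is excluded around the viewpoint, dotted lines mark elements and the green bar marks CFTR from translation start to end; the 8 libraries share a rise at +48.9 kb, and the flat ends on the right are the floors, which differ between libraries.

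At the -20.9 kb viewpoint, differences between the siRNAs at the named elements did not pass the test. The -35 kb airway enhancer held 8.51% ± 4.18 of the summed signal with NC siRNA and 6.44% ± 2.50 with BACH1 siRNA (SD, n = 2 each), and the -44 kb airway enhancer 3.88% ± 2.64 and 2.90% ± 1.39. The log2 change, BACH1 minus NC siRNA, was -0.36 ± 0.25 at -35 kb and -0.32 ± 0.40 at -44 kb (limma estimate ± SE). The promoter held 3.27% ± 1.18 and 2.93% ± 1.16 (log2 -0.17 ± 0.35). The +48.9 kb boundary element held 1.70% ± 1.06 and 2.57% ± 1.01 (log2 0.70 ± 0.41), the -80.1 kb boundary element 2.12% ± 1.57 and 1.88% ± 0.784 (log2 -0.01 ± 0.44).

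None of the lists of elements held a member past the test at this viewpoint. With limma and adjustment over the list alone, 0 of 13 elements and gene starts passed, and the smallest adjusted p was 0.601. That value was shared by -35 kb (unadjusted p = 0.150), +48.9 kb (0.0917), intron 23 (0.185) and the start of ASZ1 (0.164), a neighbouring germ cell gene. The limma-adjusted p of the 5 kb windows that hold the elements was 0.998 throughout. Both airway enhancers, the 3 measured boundary and insulator elements, the 3 intronic elements and the 2 promoter-side elements did not pass. The 95% interval of the log2 change ran from -0.86 to 0.13 at -35 kb and from -0.86 to 0.53 at the promoter. The replicates of this viewpoint also differ in library protocol, with a 2012 method in replicate 1 and a 2020 method in replicate 2 of both siRNAs. Within the 2012 pair the log2 change was -0.48 at -35 kb and 0.42 at +48.9 kb, and within the 2020 pair it was -0.25 and 0.97. At intron 1 the pairs went opposite ways, 0.25 and -0.91.

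Over all windows of the -20.9 kb viewpoint, limma called 0 of 175 changed, with 7 at an unadjusted p under 0.05. Chance over 175 windows would give 8.75, but only 63 windows were above the floor in all 4 libraries. Windows at the floor had a wide SE (over all windows the median was 1.07, against a median absolute change of 0.168). The 7 are therefore not read as fewer than chance. The smallest adjusted p was 0.903. Of the windows whose libraries did not overlap between siRNAs (17 of 175, or 9.71%), the largest changes lay inside or just past CFTR, and none was past the test. The window 117294485 to 117299484, near the 3' end of the gene body, held 0.371% ± 0.251 with NC siRNA and 1.05% ± 0.0958 with BACH1 siRNA (SD, n = 2 each; log2 1.65 ± 0.62, limma adjusted p = 0.903). The window 117189485 to 117194484 in the gene body had a log2 change of 1.50 ± 0.68, and 117339485 to 117344484, short of the +48.9 kb element, 1.38 ± 0.62. In the other direction, 117134485 to 117139484, which lies 17 kb past the translation start, held 1.93% ± 0.481 and 0.745% ± 0.159 (log2 -1.36 ± 0.53). The windows 117199485 to 117204484 and 117259485 to 117264484 had log2 changes of -1.57 ± 0.68 and -0.88 ± 0.67. For exchangeable libraries chance gives a share of 33.3% without overlap, but these are not exchangeable. Splitting them by protocol gave 82.3%, and across both siRNA and protocol 14 windows, or 8%. All these shares count windows at the floor, where the order of libraries follows their floors. Those were 0.0111% (NC) and 0.0175% (BACH1 siRNA) of the sum in replicate 1, and 0.231% and 0.191% in replicate 2. The shares therefore do not measure an effect of protocol or siRNA on contact.

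At the -80.1 kb viewpoint differences at the airway enhancers and the promoter were smaller than their standard errors with libraries scaled by their sum. The -35 kb enhancer held 4.72% ± 0.672 with NC siRNA and 4.75% ± 0.0347 with BACH1 siRNA (SD, n = 2 each; log2 0.01 ± 0.25), with a 95% interval of the fold change from 0.716 to 1.42. The -44 kb enhancer held 1.81% ± 0.0345 and 1.59% ± 0.542 (log2 -0.23 ± 0.40), and the promoter 3.14% ± 0.513 and 2.83% ± 0.193 (log2 -0.14 ± 0.35). Contact with the -20.9 kb insulator was 2.52% ± 0.334 and 1.82% ± 0.799 (log2 -0.53 ± 0.42), and with the +48.9 kb boundary 2.21% ± 0.0510 and 2.52% ± 0.287 (log2 0.19 ± 0.41). The lowest p among the elements belonged to intron 1, with 2.52% ± 0.502 and 1.45% ± 1.01 and a log2 change of -0.97 ± 0.45.

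That intron 1 difference had an unadjusted limma p of 0.0304 and did not pass adjusted over the list alone (0.395) or as a window (0.971). It rested on BACH1 siRNA replicate 1, with 0.738% against 2.17% in replicate 2 and 2.16% and 2.87% in the NC siRNA libraries. With replicate 2 left out it passed (log2 -1.74, limma adjusted p = 0.00555, the lowest over its alternatives, where it ran up to 1). With each library centred on its median instead, all elements of this viewpoint moved by -0.73, to -0.72 ± 0.65 at -35 kb and -0.87 ± 0.84 at the promoter, and none passed. The median was itself a floor value in every library of this viewpoint except BACH1 siRNA replicate 2 (27.3% to 46.6% of windows above the floor, against 63.6%). The shift thus largely follows the heights of the floors. In all, 0 of 13 elements and gene starts passed with limma. Both airway enhancers, the 3 measured boundary and insulator elements, the 3 intronic elements and the 2 promoter-side elements did not pass. Log2 changes ran from -0.53 to 0.68 among the boundary and insulator elements. The 0.68 ± 0.64 was at +6.8 kb, whose position is approximate. In the tested window 117309485 to 117314484, which also holds that element, the log2 change was -0.58 ± 0.56, so its sign is not settled.

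Over all windows of the -80.1 kb viewpoint, limma called 0 of 175 changed, with 0 at an unadjusted p under 0.05. The smallest adjusted p was 0.971. Without BACH1 siRNA replicate 1 the count was 66, all lower, and 61 of these windows were above the floor in none of the 4 libraries. Among windows whose libraries did not overlap (22 of 175, or 12.6%, against 69.1% with the libraries split by replicate and 18.3% across siRNA and replicate), the largest changes were log2 1.19 ± 1.11 at 116984485 to 116989484, 1.17 ± 0.84 at 117269485 to 117274484 and 1.08 ± 0.67 at 117329485 to 117334484. These 3 windows were above the floor in 1, 1 and 2 of the 4 libraries. The shares without overlap count windows at the floor, whose order follows the floors, and only 47 windows were above it in all 4 libraries. In the other direction, the window 117144485 to 117149484 at 27 kb past the translation start held 1.30% ± 0.0144 with NC siRNA and 0.725% ± 0.268 with BACH1 siRNA (SD, n = 2 each; log2 -0.88 ± 0.49, limma adjusted p = 0.971). The windows 117204485 to 117209484 and 117284485 to 117289484 had log2 changes of -0.82 ± 0.64 and -0.96 ± 0.69, and the latter overlaps the intron 23 element. In the window centred on that element, shifted by 1 kb, signal was 0.205% ± 0.0991 and 0.197% ± 0.0503 (log2 0.00 ± 0.71).

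**Figure D2:**
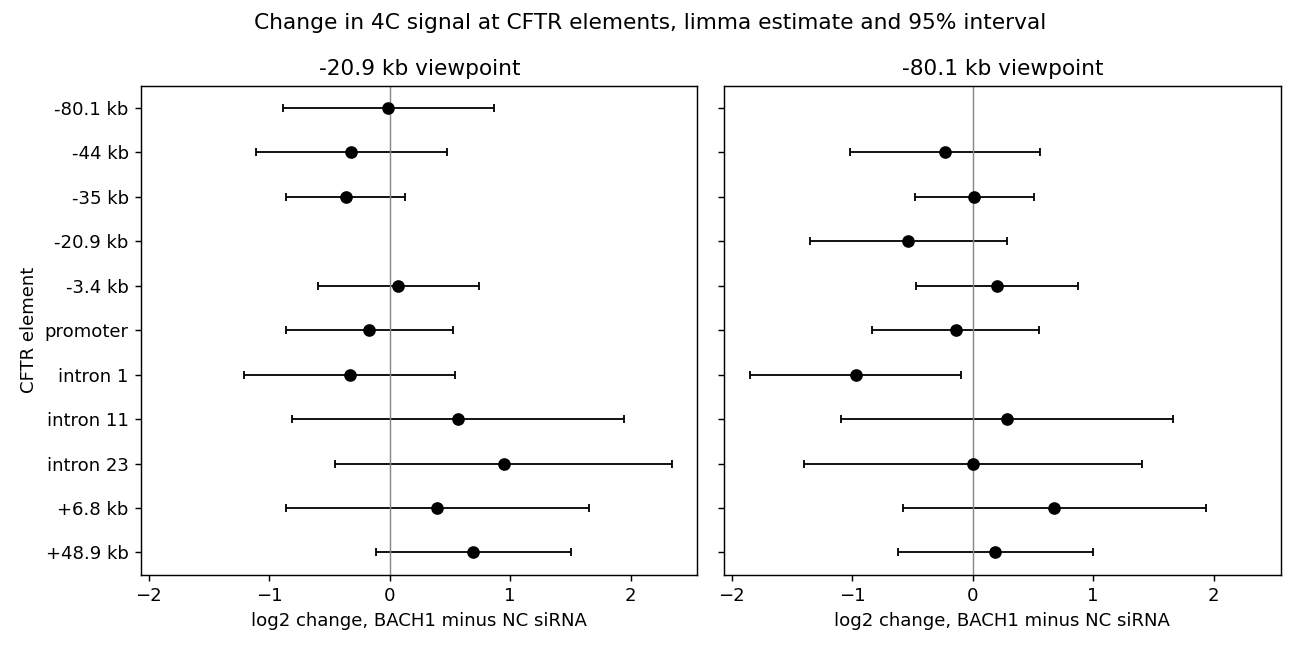
Log2 change in 4C signal at the CFTR elements, BACH1 minus NC siRNA (x axis), for each element (y axis) at the -20.9 kb viewpoint (left) and the -80.1 kb viewpoint (right). Points are limma estimates and bars their 95% intervals before adjustment; an element within 10 kb of its own viewpoint has no point, and only intron 1 at the -80.1 kb viewpoint, from -1.85 to -0.09, has an interval that leaves out 0.

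The effect of the siRNA did not differ past the threshold between viewpoints in any window or element. Limma called 0 of 171 windows, with 4 at an unadjusted p under 0.05 and a smallest adjusted p of 0.998. Among 12 elements and gene starts measured at both viewpoints, 0 passed, and the smallest p adjusted over the list alone was 0.954. The largest gaps in SE terms were at -35 kb (log2 difference -0.38 ± 0.36) and intron 1 (0.64 ± 0.63). Signal at the start of WNT2 was above the floor in 0 of 4 libraries at either viewpoint, so no change can be read there. At the start of CTTNBP2, whose position is approximate, the answer turned on 1 kb. The centred window was above the floor in 0 of 4 libraries at -20.9 kb, and the tested window 117509485 to 117514484 in 4 of 4, with a log2 change of -0.63 ± 1.08 (limma adjusted p = 0.998).

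With all windows counted, the share of signal in each part of the locus overlapped between the siRNAs at both viewpoints. These shares include windows at or below the floor, which held 32.2% of the sum in BACH1 siRNA replicate 1 at -80.1 kb and 0.636% in replicate 2. In that replicate 1, the share beyond +48.9 kb was 18.6% with all windows counted and 4.05% with only those above the floor. Part of the spread between libraries is thus that of their floors. From -20.9 kb, the gene body held 24.5% ± 2.67 with NC siRNA and 27.3% ± 2.37 with BACH1 siRNA (SD, n = 2 each; exact permutation p = 0.667, two-sided). The stretch from the 3' end to +48.9 kb held 8.83% ± 4.07 and 11.6% ± 1.60 (exact permutation p = 0.667), and the stretch from -20.9 kb to the promoter held 11.6% ± 2.52 and 9.83% ± 2.52 (exact permutation p = 0.667). From -80.1 kb, the gene body held 23.7% ± 2.54 and 20.2% ± 4.85 (exact permutation p = 0.667), and the stretch from the 3' end to +48.9 kb held 7.87% ± 0.677 and 7.82% ± 1.85 (exact permutation p = 1). All 12 of these tests had a Benjamini-Hochberg adjusted p of 1, and 2 against 2 cannot go below an exact permutation p of 0.333. The permutation takes no account of the protocol pairs of the -20.9 kb viewpoint. Within the 2012 and the 2020 pair, BACH1 minus NC siRNA was -1.79 and -1.78 percentage points from -20.9 kb to the promoter. From the 3' end to +48.9 kb it was 0.976 and 4.47. Outside the excluded zone, the stretch to the promoter held only the windows 117109485 to 117114484 and 117114485 to 117119484. In the 2020 pair these went opposite ways, from 7.17% to 4.53% and from 2.65% to 3.52%. The difference for this stretch changed sign in 2 of 8 alternatives (-3.78 to 0.000633 percentage points). With only windows above the floor counted, a setting chosen after seeing the data, the siRNAs did not overlap in 4 of the 12 intervals, each at the smallest exact permutation p of 0.333 (adjusted 0.889). From -20.9 kb these were the stretch from -20.9 kb to the promoter (13.1% ± 0.545 with NC siRNA, 10.8% ± 1.39 with BACH1 siRNA) and that from the 3' end to +48.9 kb (9.62% ± 3.11 and 12.8% ± 0.121). From -80.1 kb they were the stretch upstream of -80.1 kb (13.2% ± 0.675 and 15.4% ± 0.731) and the gene body (25.7% ± 1.78 and 20.6% ± 4.61; SD, n = 2 each). For exchangeable libraries chance gives 33.3% without overlap, so 4 of 12 is no excess.

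The most alike libraries of each viewpoint had different siRNAs. Across windows, which are not independent replicates, the log2 profiles of the -20.9 kb viewpoint correlated with Pearson r = 0.892 (Spearman 0.854) between the NC siRNA libraries and 0.905 (0.842) between the BACH1 siRNA libraries. The highest value, 0.953 (0.893), joined NC and BACH1 siRNA replicate 1, which share the 2012 protocol. At the -80.1 kb viewpoint the values were 0.894 (0.852) between NC siRNA libraries and 0.755 (0.810) between BACH1 siRNA libraries, and the highest, 0.934 (0.903), joined replicate 2 of the 2 siRNAs. Over windows above the floor in both libraries of a pair, the BACH1 siRNA libraries of the -80.1 kb viewpoint correlated at 0.860 (0.867) and the NC siRNA libraries at 0.877 (0.855), and pairs of different siRNAs at 0.767 (0.782) to 0.896 (0.875). At -20.9 kb the same values were 0.787 (0.782), 0.747 (0.697) and 0.674 (0.646) to 0.872 (0.860).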

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

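The floor alternatives, the scaling by the sum above the floor and the upper value were chosen after seeing the data. The count of changed windows was 0 under 23 of 24 alternatives at each viewpoint and 26 of 27 for the difference between viewpoints. With every value raised to 1 common floor over all libraries, 1 window was called at -20.9 kb and 1 in the difference. It was the same window, 117279485 to 117284484 (log2 0.99 ± 0.03, against 1.44 ± 0.68 at -20.9 kb in the main fit). The common floor of 0.269% gave all libraries at -80.1 kb the same value there. It also raised NC siRNA replicate 1 at -20.9 kb from 0.134%. The SE of 0.03 thus follows from the rule and does not measure the spread of contact signal. Leaving out 1 library gave 0 to 66 windows at -80.1 kb, the 66 without BACH1 siRNA replicate 1, and 0 to 1 elements, the 1 being intron 1 at -80.1 kb without BACH1 siRNA replicate 2, which leaves that arm its low library alone (0.738% against 2.17%). A group left with 1 library is assumed to vary like the others. Of the 66 windows, 98.5% had both NC siRNA libraries at or below their floor, so the count follows the height of the floor in the remaining BACH1 siRNA library, a test set before that share was computed.

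Pairing by neighbouring library numbers called 0 windows and 0 elements, as did the fit without the protocol term (no replicate block). At -80.1 kb this pairing rests on the numbers alone, and deviations of the paired libraries correlated at -0.234. The smallest adjusted p at -20.9 kb ran from 0.00495 to 1 over the alternatives and was 0.0986 without the filter, which adds 1 window at 0 in every library. Some scalings move all elements of a viewpoint together: median centring shifted their log2 changes by -0.73 at -80.1 kb, and values as deposited by a median of 0.27 at -20.9 kb and -0.28 at -80.1 kb. The medians were floor values in all libraries but BACH1 siRNA replicate 2 at -80.1 kb, so median centring largely aligns floors. Apart from alternatives that rescale libraries, 65 of 483 element values had the opposite sign to the reported one, and none of these passed. The sign held under all 23 alternatives for 3 of 26 element changes: +48.9 kb at -20.9 kb (0.05 to 0.97), and -20.9 kb (-1.27 to -0.07) and intron 1 (-1.74 to -0.09) at -80.1 kb. Interval differences moved by more than the replicate spread in 1 of 96 cases, but that spread is wide: 10 of 12 changed sign under some alternative (19 cases), with values from -11.1 to 8.73 percentage points. Depth is unknown, and the floors limit what can be read outside the CFTR domain.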

Other observations

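The tests here were chosen after the values were seen. Set against the 5 kb windows 10 kb to either side, the +48.9 kb element stood out from both viewpoints: log2 2.36 ± 0.61 from -80.1 kb and 1.60 ± 1.04 from -20.9 kb (SD, n = 4), above its flanks in 4 of 4 libraries each. By siRNA this was 0.82 ± 0.42 with NC and 2.38 ± 0.79 with BACH1 siRNA from -20.9 kb, and 1.95 ± 0.57 and 2.78 ± 0.30 from -80.1 kb (SD, n = 2 each; exact permutation p = 0.333 each, the smallest possible). From -80.1 kb, the -35 kb enhancer stood 1.05 ± 0.44 above its flanks and the promoter 0.98 ± 0.66, in 4 of 4 libraries each, with the promoter at 0.51 ± 0.14 with NC and 1.44 ± 0.67 with BACH1 siRNA (exact permutation p = 0.333). That gap lies in the flanks: the promoter itself held 3.14% and 2.83%, its upstream flank 1.85% and 0.766%, and its downstream flank, the intron 1 element, 2.52% and 1.45%. From -20.9 kb the promoter lay below its flanks in 4 of 4 libraries (-0.70 ± 0.50), with its upstream flank next to the excluded stretch. The -44 kb enhancer lay below its flanks from both, at -1.33 ± 0.39 and -0.51 ± 0.20, in 4 of 4 libraries each, but its downstream flank holds the high -35 kb signal. The start of ASZ1 lay below its flanks in 4 of 4 libraries from both, less so with BACH1 siRNA (-1.23 and -0.54 from -20.9 kb, -0.83 and -0.61 from -80.1 kb; exact permutation p = 0.333 each). In all, 5 of 24 such comparisons reached the smallest exact permutation p, where 8 would by chance for exchangeable libraries. The -20.9 kb insulator, seen from -80.1 kb, did not stand apart (-0.22 ± 0.62). Positions of elements are good to about 1.1 kb, and that of +48.9 kb is less certain.

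The siRNA effects of the viewpoints were weakly related across windows, which are not independent. The log2 changes correlated with Pearson r = 0.123 (Spearman 0.159) over the 62 windows above the floor in at least 6 libraries, and 34 of the 62 had the same sign. The files of replicate 2 at -80.1 kb reach 100 kb further upstream. There NC siRNA had 0 of 98 positions above its floor and BACH1 siRNA had 5, all below the NC siRNA floor.

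Both viewpoints had lower signal with BACH1 siRNA from 117129485 to 117139484, in the first intron of CFTR. At -20.9 kb the windows on either side went the other way (log2 0.53 ± 0.46 and 0.43 ± 0.54), and at the intron 1 element the protocol pairs differed in sign (0.25 and -0.91), while at -80.1 kb both neighbours were lower too (-0.43 ± 0.46 and -0.52 ± 0.54). From -20.9 kb the mean of these windows was 2.06% and 2.05% with NC siRNA and 1.17% and 0.882% with BACH1 siRNA, and from -80.1 kb 1.55% and 2.01% against 0.724% and 1.40%. A scaling factor moves all windows alike, and the other windows above the floor had median log2 changes of 0.22 ± 0.64 at -20.9 kb and -0.12 ± 0.51 at -80.1 kb (SD across windows). The pattern, at -1.04 and -0.76, lay at least 1.26 of these SDs lower. Since its windows were chosen for being lower, a gap below the others was fixed by the choice. It therefore does not decide whether scaling by the summed signal plays a part. The size of the pattern depended on the scaling: under the others it ran from -1.49 (median centring, which largely aligns floors) to -0.42 (quantile normalization) at -80.1 kb and from -1.18 to -0.78 at -20.9 kb. At -80.1 kb much of the change came from 1 library: without BACH1 siRNA replicate 1 it was -0.32 ± 0.54 against -0.76 with it, while the -20.9 kb change of -1.04 does not involve that library. As a hypothesis, BACH1 knockdown may lower contact there, but the windows were chosen for the pattern. The exact stratified permutation p of 0.0556 is the smallest that 36 arrangements allow. These arrangements take no account of the protocol pairs of the -20.9 kb viewpoint, so the hypothesis stays open.

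The floor differed between libraries. Library protocol was argued against as the whole cause, since the libraries of the 2012 protocol alone spanned 35.2-fold. A part for protocol is not excluded. The 2 libraries of the 2020 protocol had the highest floors in deposited units, 0.0156 and 0.0154 (1.01-fold apart), against at most 0.00967 with the 2012 protocol. As percent of the summed signal this order did not hold. There the highest floor was 0.269%, in BACH1 siRNA replicate 1 at -80.1 kb, of the 2012 protocol. The libraries of the 2020 protocol had 0.231% and 0.191%. The floors were not ordered by siRNA: at -80.1 kb those of 2 of 2 NC siRNA libraries lay between those of the BACH1 siRNA libraries. At -20.9 kb the floor with BACH1 siRNA was higher in the 2012 pair (0.000734 against 0.000384) and lower in the 2020 pair (0.0154 against 0.0156). An order among so few libraries can arise by chance, so it does not decide whether BACH1 siRNA plays a part. Sequencing depth, which is unknown here, was not tested and stays open.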
